A study of Rattus norvegicus with 9 samples.

How the data were processed

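Genomic DNA of N27 cells, a rat dopaminergic neural line, was measured in 3 groups of 3 arrays: untreated cells, cells given manganese (Mn) and cells given MPP+, the toxic metabolite of MPTP. Per the labels, replicates are independent and doses were below lethal ones, and no dose was given in the labels used here. Sheared and denatured DNA was bound to a rat gene expression array, and methylated cytosine on the bound DNA was stained with an antibody and a Cy3-labelled secondary antibody. The Cy3 channel was used throughout, in which a spot's brightness is a relative methylation signal with no absolute scale. The outputs of replicate 3 of each group carry a second channel, and the labels do not say what it holds.

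The authors deposited 1 scanner output per array, in which spot and local background intensity values are given on a linear scale with no normalization recorded in the columns, per the file headers. Per the labels, acquisition and normalization used the ScanArray software, and the version is not given in the sources used here. Per the file headers, each spot also carries the percent of saturated pixels, a signal to noise ratio, a diameter and a quality code. The authors also deposited a value table, whose values are the signal to noise ratio of 1 spot per probe, the spot median divided by the SD of the local background, within a tolerance of 0.006. This was shown for every column but that of Mn replicate 3, whose values match no array given (at most 4.61% of them). That table has no centring and no background subtraction, its lowest value is 1, and 9 of its values equal the largest single-precision number. Its column medians were 2.39, 2.67 and 1.78 in control replicates 1 to 3, 2.51, 2.17 and 1.80 in Mn, and 2.25, 2.27 and 1.93 in MPP+.

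Each array held 45220 spots, of which 42877 belonged to 30367 gene probes and 966 (2.14%) had no identifier. Of the gene probes, 28977 had 1 spot and 1390 had 10 spots. RefSeq accessions in the scanner output were matched without versions to a reference gene table: 18438 probes had 1 symbol (15507 symbols), 11929 had no symbol matched and 4332 carried no accession. Some members entered a gene list through an older symbol, among them Ppil3 among the cytochrome P450 genes and Cdhr1 and Dchs1 among the protocadherins. No genome was used here, so no coordinates are given.

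The scanner outputs labelled control replicate 3 and Mn replicate 3 held equal values at every spot, while no other pair of arrays had equal spot medians at more than 0.677% of spots. By a rule set beforehand, arrays that share their values across groups left every fit but the alternatives that put them back. This kept 2 control, 2 Mn and 3 MPP+ arrays. The Cy3 median of each spot was corrected with normexp (offset 50) on the local background median and set to log2. Gene spots were quantile normalized between arrays, and spots of a probe were averaged. limma 3.58.1 in R 4.3.3 fitted 1 mean per group with no block, and eBayes with Benjamini-Hochberg adjustment at 0.05 tested Mn against control, MPP+ against control and Mn against MPP+. A probe was tested if its spot median exceeded the background median by over 2 background SDs on at least 3 of the 7 arrays, which left 45 probes. The rule for leaving out spots the scanner marked as bad could not be applied, because no source used here says what the codes mean. Leaving out code 4 or code 1, and the place of an array along the slide as a random block, were added as alternatives after the data were seen. Camera (inter-gene correlation 0.01), camera with an estimated correlation and fry tested 29 gene lists with at least 5 genes, with 1 probe per gene, the brightest on average. Where a probe was not above background on any array of a group, a fold is written as "at least". It sets the other group's mean against the lowest signal above background on each array, or the measured signal where higher. That mean takes in all arrays of the brighter group, also those where the probe was not above background. The fold thus allows for the dim group alone and is no lower bound on a change where the brighter group has such arrays. Other tables and tests used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

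The design, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named, where fewer than 5 probes passed, the 10 genes of smallest p per comparison, 5 in each direction, and 15 genes of dopamine, Parkinson disease, metal transport and DNA methylation wherever measured. Not every gene so named is reported here. Alternatives were another offset or no background correction, the spot mean, median centring, cyclic loess, no filter on dim probes, a replicate block, a scan batch block, fewer or all 9 arrays, array weights, a trended robust variance, the authors' value table, and each array left out in turn. Signal levels of whole arrays were compared before normalization with exact two-sided permutation tests. Agreement of the 10 spots of a probe was measured as an intraclass correlation with 1000 bootstrap draws over probes.

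The steps were tested on simulated data made from the fitted spread. In 3 simulated sets of all 30367 probes for Mn against control, limma called 45.3% of the probes changed by a log2 of 2 and 80.7% of those changed by 4. In 50 simulated sets of the 45 probes of the same comparison, it called 10% and 52%. Camera called a mitochondrial complex I shift of log2 0.25 in 20 of 20 simulated sets for Mn against control. All 35 genes of that list were moved alike with independent noise, and no other list was simulated. An intraclass correlation planted at 0.05 was read as 0.0592 (0.0490 to 0.0708). The number of arrays limits the precision of every value.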

Results

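DNA methylation was profiled in N27 cells, a rat line of dopaminergic neural origin, after exposure to manganese or to MPP+, a poison of mitochondrial complex I. The comparisons ask which genes carry more or less methylated DNA after each toxicant, and whether the toxicants differ. Each group had 3 arrays. Control replicate 3 and Mn replicate 3 held equal values, so values below rest on control (n = 2), Mn (n = 2) and MPP+ (n = 3).

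Genes of the dopamine system gave no signal above the local background on most arrays. Of the 15 genes named beforehand, 14 had a probe, and 13 of their 18 probes exceeded background by over 2 SDs on none of the 7 arrays. The same held for 24090 of all 30367 gene probes (79.3%), so it was not particular to these genes. Th, the rate-limiting enzyme of dopamine synthesis, had a median spot over background of 1.03. Slc18a2, the vesicular monoamine transporter, stood at 1.29, and Maoa and Maob, which break down dopamine, at 0.948 and 1.04. Slc6a3, the dopamine transporter, was above background on control replicate 2 alone, with a median of 0.846. Of the Parkinson disease genes, Pink1 and Lrrk2 had medians of 1.08 and 1.01, and the 3 probes of Park7 ranged from 0.900 to 1.27. Sod2, the mitochondrial superoxide dismutase, exceeded background on Mn replicate 1 alone (median 1.13). Slc11a2 and Slc39a14, which carry divalent metals, each had 1 of 2 probes above background on 1 MPP+ array, with medians of 0.838 and 1.28 for those probes. Dnmt1 and Dnmt3a, which methylate DNA, were at 0.993 and 0.947 and above background on no array.

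Over whole arrays the spots were dim. The median spot was 187.5 ± 27.6 in control (SD, n = 2), 176.5 ± 10.6 in Mn (SD, n = 2) and 222 ± 22.5 in MPP+ (SD, n = 3), against median backgrounds of 172 ± 21.2, 163.5 ± 3.54 and 207.7 ± 18.9. Gene spots above background made up 4.00% ± 0.447 of spots in control, 4.10% ± 0.876 in Mn and 2.54% ± 0.762 in MPP+ (SD). Over the 7 arrays together this was 3.40% of gene spots, and 3.11% of dark corner and negative control spots, which are made to bind nothing (95% Wilson interval 2.68 to 3.62, counting error only). On control replicate 2 the gene spots (3.69%) lay above that array's interval for blank spots (1.10 to 3.08). The array medians of log2 spot over background ran from 0.067 to 0.14.

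**Figure D1:**
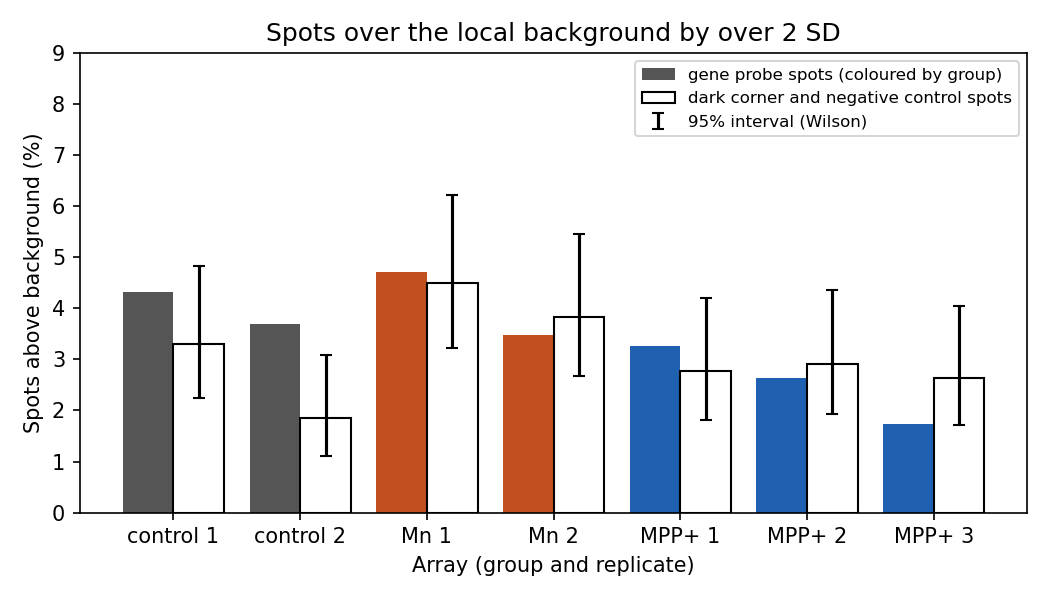
Percent of spots over the local background by over 2 background SDs on each of the 7 arrays, for gene probes (filled bars, coloured by group) and for dark corner and negative control spots (open bars, 95% Wilson interval). Gene spots range from 1.74% on MPP+ replicate 3 to 4.72% on Mn replicate 1, and leave the interval of the blank spots upward on control replicate 2 alone.

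Of 30367 probes, 24090 (79.3%) were above background on no array and 45 on at least 3 arrays, where 34.4 would be reached by arrays that pass probes independently. The 60 probes above background on both control arrays compare with 46.4 from independent arrays, the 53 on both Mn arrays with 48.8, and the 0 on all 3 MPP+ arrays with 0.401. Among the 29 gene lists, Or6al2, an olfactory receptor, was the single member above background on at least 3 arrays.

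Mn against control asked which genes manganese moved. No gene passed limma's threshold. The smallest p was at Higd1a, a hypoxia-induced protein of the inner mitochondrial membrane, whose log2 signal was 6.92 ± 0.400 in Mn (SD, n = 2) and 10.3 ± 4.03 in control (SD, n = 2), at least 9.05-fold brighter in control (adjusted p = 0.523). Lower values in Mn also stood at Rcor3, a corepressor of the REST family (at least 3.83-fold), Rin3, an exchange factor of early endosomes (at least 3.16-fold), Tll1, a metalloprotease (at least 2.30-fold), and Rnase4, a secreted ribonuclease (log2 -2.04 ± 1.33 SE). Higher values in Mn stood at Snx29, a sorting nexin (2.43 ± 1.17), Taf5l1, a member of histone acetylating complexes (2.53 ± 1.31), Ctc1, a telomere protein (1.17 ± 1.15), Klhl9, an adaptor of a ubiquitin ligase (at least 3.27-fold), and Zfyve19, a FYVE zinc finger protein (at least 2.05-fold), with adjusted p from 0.719 to 0.843 over these 5. The folds of Tll1 and Zfyve19 rest on 1 array above background of the 2 in the brighter group. limma called 0 of 45 probes, with 2 at an unadjusted p under 0.05, and 0 of 30367 with no filter on dim probes, with 1170 (3.85%) under 0.05. The filtered test would find few changes of this kind: 30% of simulated changes of log2 3 were called over 45 probes. Without control replicate 2, Rnase4 passed (log2 -5.17 ± 1.35 SE, adjusted p = 0.00686), and without Mn replicate 1, Taf5l1 passed (5.50 ± 1.49, adjusted p = 0.00925), each resting on 1 bright array.

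**Figure D2:**
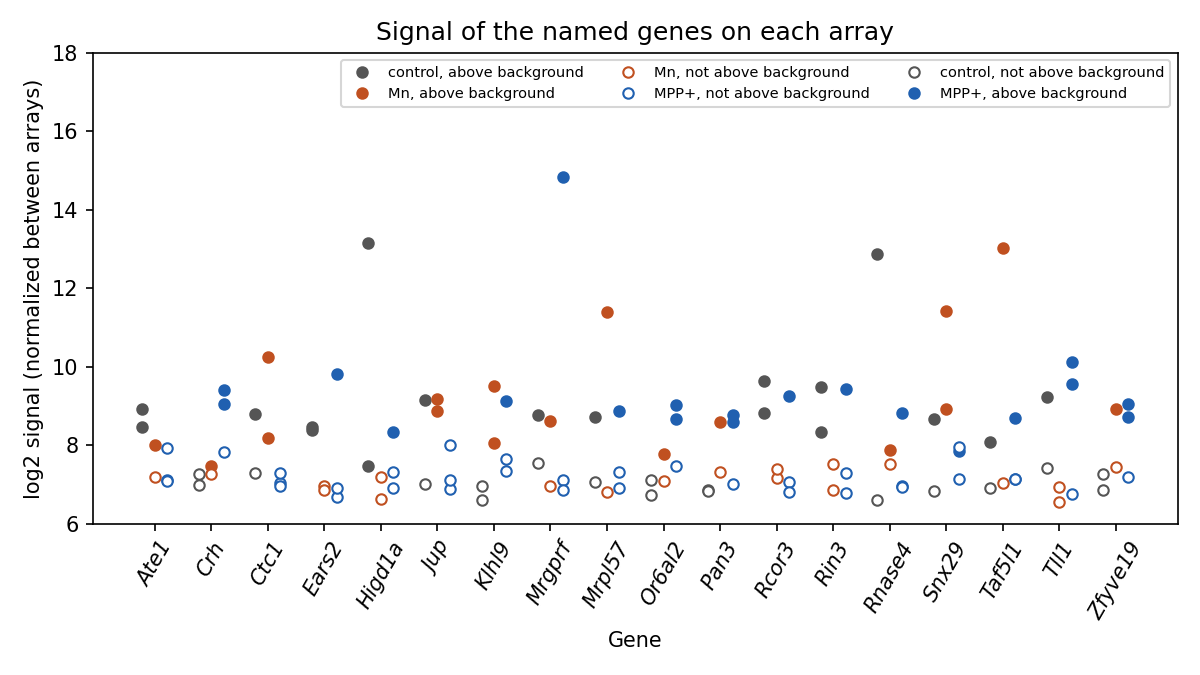
Normalized log2 signal of the 18 genes of smallest p on each of the 7 arrays (points, coloured by group), filled where the probe was above background on that array. In several genes 1 array stands far above its group: Higd1a stood at 13.2 on control replicate 2 and at 7.47 on control replicate 1, and Taf5l1 at 13.0 on Mn replicate 2 and at 7.03 on Mn replicate 1.

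No gene list could be tested among the 45 filtered probes, so lists were read over all probes, where most members lie at background. Camera called 0 of 29 lists in Mn against control; 2 had an unadjusted camera p under 0.05, and fry called 0 with 2 under 0.05. Parkinson disease genes had the smallest camera p: 11 of 15 genes had higher values in Mn, with a median log2 shift of 0.26 (adjusted p = 0.347 with camera). The adjusted p for that list was 0.911 with an estimated correlation and 0.407 with fry. With fry the smallest p was at proteasome and ubiquitin genes (16 of 43 higher in Mn, median -0.061, adjusted p = 0.290 with fry). Genes of mitochondrial dynamics and biogenesis had a median of -0.13, the unfolded protein response -0.12, inflammation -0.096, apoptosis genes -0.032 and neuronal cytoskeleton genes -0.029. Cell cycle and DNA damage genes stood at -0.027, antioxidant and glutathione genes at -0.019, autophagy and lysosome genes at -0.012, olfactory receptors at -0.012, glial and immune markers at -0.0045 and presynaptic genes at -0.0017. Dopamine synthesis, storage and breakdown genes stood at 0.0039, genes of manganese, iron and zinc handling at 0.0078, voltage-gated channels at 0.0092, neurotrophic factors at 0.020, respiratory complexes II to V at 0.022, glutamate and GABA receptors at 0.023 and the DNA methylation machinery at 0.024. Imprinted genes stood at 0.026, mitochondrial complex I at 0.031, cytochrome P450 genes at 0.043, midbrain dopaminergic transcription factors at 0.049, homeobox genes at 0.060, protocadherins at 0.068, ribosomal proteins at 0.069, histones at 0.092 and vomeronasal receptors at 0.094. Adjusted over the list alone, limma passed H2bu1, a histone (at least 4.10-fold brighter in control), and Asb4, an imprinted gene (at least 3.69-fold brighter in control), above background on 2 arrays and 1 array, all of control. It also passed Syn1, which encodes a synaptic vesicle protein, and Uba1, the main ubiquitin-activating enzyme, but both were above background on 0 arrays, so these calls compare unmeasured levels and no fold is given. The p of these genes adjusted over all genes was 0.382 to 0.392 with limma.

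MPP+ against control asked the same of MPP+. No gene passed limma's threshold. Higher values in MPP+ stood at Crh, corticotropin-releasing hormone (8.77 ± 0.831 in MPP+, SD, n = 3, and 7.14 ± 0.201 in control, SD, n = 2, at least 3.05-fold), the olfactory receptor Or6al2 (at least 2.43-fold), Pan3, a regulator of poly(A) tail removal (at least 2.07-fold), Zfyve19 (at least 2.25-fold) and Klhl9 (at least 1.95-fold). Lower values stood at Higd1a (log2 -2.78 ± 1.18 SE), Rnase4 (-2.17 ± 1.21), Rcor3 (-1.52 ± 1.06), Rin3 (-1.08 ± 1.07) and Ate1, an arginyl-transferase (at least 2.50-fold brighter in control). The adjusted p was 0.790 for all 10. Of the 3 MPP+ arrays, 2 were above background for Crh, Or6al2, Pan3 and Zfyve19, and 1 for Klhl9. limma called 0 of 45 probes, with 1 at an unadjusted p under 0.05, and 0 of 30367 with no filter, with 948 (3.12%) under 0.05. Without control replicate 2, which left 1 control array, Rnase4 stood at log2 -5.31. In the authors' deposited table Egf, a growth factor, passed (log2 -1.97 ± 0.497 SE, adjusted p = 0.0491 with limma, 380 probes tested). That fit used all 3 columns of each group, with the shared array as control replicate 3. Its values are unnormalized log2 signal to noise ratios of 1 spot per probe, so it is not like the fits above.

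Camera called 0 of the 29 lists in MPP+ against control, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.951. Genes of manganese, iron and zinc handling had the largest median shift (0.16, 26 of 43 genes with higher values), followed by midbrain dopaminergic transcription factors (0.13, 9 of 12) and presynaptic genes (0.13, 20 of 30). Mitochondrial complex I, which MPP+ blocks, had a median of -0.016, with 16 of 35 genes higher. Dopamine genes stood at -0.019, with 11 of 22 higher. Adjusted over the list alone, limma passed Asb4 (at least 3.60-fold brighter in control, above background on 1 control array), and again Syn1 and Uba1, which were above background on 0 arrays and have no fold. Their p adjusted over all genes ran from 0.460 to 0.678 with limma, and both toxicants share the control arrays behind these values.

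Mn against MPP+ tested the difference between the toxicants. No gene passed limma's threshold. Higher values in Mn stood at Snx29 (log2 2.53 ± 1.07 SE), Taf5l1 (2.37 ± 1.20), Mrpl57, of the mitochondrial ribosome (1.41 ± 1.15), Ctc1 (at least 4.23-fold) and Jup, which encodes a protein of cell junctions (at least 3.11-fold). Lower values in Mn stood at Mrgprf, a receptor of the Mas-related family (log2 -1.82 ± 1.37 SE), Crh (-1.41 ± 1.04), Or6al2 (-0.96 ± 1.04), Tll1 (at least 3.21-fold brighter in MPP+) and Ears2, the mitochondrial glutamyl-tRNA synthetase (at least 1.59-fold). The adjusted p over these 10 ran from 0.605 to 0.960 with limma. Of the 3 MPP+ arrays, 2 were above background for Tll1 and 1 for Ears2. limma called 0 of 45 probes, with 2 at an unadjusted p under 0.05, and 0 of 30367 with no filter, with 1029 (3.39%) under 0.05. Camera called 0 of 29 lists, with 1 at an unadjusted p under 0.05: Parkinson disease genes had the smallest p (median log2 0.28, 11 of 15 genes higher in Mn, adjusted p = 0.184, and adjusted p = 0.828 with an estimated correlation). Genes of manganese, iron and zinc handling had a median of -0.16 (15 of 43 higher, adjusted p = 0.708 with camera). Without Mn replicate 1, Taf5l1 passed (5.33 ± 1.40, adjusted p = 0.00664 with limma).

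Log2 changes under Mn and MPP+ correlated across the 45 probes (Pearson 0.592, Spearman 0.552), and genes are not independent replicates. Both comparisons use the same control arrays, and unchanged groups simulated against them gave 0.536 ± 0.145 (SD, 100 draws). The covariance was 0.791, and 0.805 in the simulation. Over all 30367 probes the correlation was 0.554 and the simulated one 0.549, with covariances of 0.146 and 0.145. With 0 calls in each comparison there was no overlap of calls to compute.

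Array level was compared as each array's median log2 signal before normalization. On the arrays used, median spot over background ran from 1.048 to 1.104 for gene spots and from 1.028 to 1.076 for dark corner spots. Array level thus cannot tell methylated DNA from background left after correction, and is not read as overall methylation. It was 7.12 ± 0.193 in control (SD, n = 2), 6.98 ± 0.155 in Mn (SD, n = 2) and 7.05 ± 0.342 in MPP+ (SD, n = 3). Mn differed from control by -0.14 (exact permutation p = 0.667, two-sided, with 0.333 the smallest possible), which ran from -0.28 to -0.0035 when 1 array was left out and was -0.064 without background correction. MPP+ differed from control by -0.069 (exact permutation p = 1, with 0.2 the smallest possible), a sign that turned without background correction (0.20) and within the arrays of 1 channel (0.052). Replicate 1 had the highest such signal in each group. Between arrays of equal replicate number, Mn differed from control by -0.17 and -0.11, and MPP+ by 0.19 and -0.082. By scan coordinates, the control arrays used lay at place 4 along the slide, those of Mn at place 3, MPP+ replicates 1 and 2 at place 1 and MPP+ replicate 3 at place 2. No place held more than 1 group, so here and in every comparison above a difference between groups can also be one between places.

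The authors' deposited table lists 1585 probes: 777 for control, 932 for Mn and 885 for MPP+, each with values for all 3 arrays of its group, where those of Mn replicate 3 match no array given. Of the complex I subunits, Ndufa6, Ndufb9, Ndufs3 and Ndufv2 were listed for every group and Ndufa13, Ndufb3 and Ndufb5 for Mn alone. In control, Mn and MPP+ in turn (SD, n = 3), mean ratios were 6.16 ± 5.50, 2.28 ± 0.633 and 3 ± 0.799 for Ndufa6, and 2.24 ± 1.40, 3.62 ± 1.56 and 1.93 ± 0.620 for Ndufb9. They were 2.10 ± 1.56, 2.01 ± 0.521 and 1.61 ± 0.679 for Ndufs3, and 3.62 ± 1.82, 1.91 ± 0.621 and 1.42 ± 0.181 for Ndufv2. Of the antioxidant genes, Gpx1 and Gsta1 were listed for every group, Glrx, Txn1 and Txnrd1 for Mn alone, and Hmox1, Slc7a11, Mgst1 and Gstm2 for MPP+ alone. The dopamine receptor Drd2 was listed for every group, with 3.23 ± 1.75 in control, 1.36 ± 0.323 in Mn and 3.69 ± 1.25 in MPP+ at 1 of its 2 probes. Its other probe was listed for Mn (1.73 ± 0.280) and MPP+ (1.61 ± 0.496) and not for control. Each complex I and Drd2 ratio above is from 1 spot per array of a probe with 10 spots, with no background subtracted. The array median of that ratio ran from 1.28 to 1.49 on the arrays used in the fits. The means of 1.36 (Drd2 in Mn) and 1.42 (Ndufv2 in MPP+) lie in that range, as a typical dim spot does. Group means of single spots are thus not read as gene levels. The metallothionein Mt2A was listed for Mn (2.45 ± 1.20) and MPP+ (2.19 ± 0.191), and its transcription factor Mtf1 for Mn alone (3.35 ± 1.43). The neurotrophic factors Bdnf, Cntf and Fgf2, the interleukins Il1b and Il6, and the synaptic genes Snap25 and Vamp1 were listed for both toxicants and not for control. That pattern held for 221 of the 1585 probes listed, and 214 were listed for control alone. The listed probes of Bdnf, Cntf, Fgf2, Il1b, Il6, Snap25 and Vamp1 have 10 spots. Those of Ndufa13, Txnrd1, Mgst1 and Gstm2 have 1 spot. Of the 1390 probes with 10 spots, 672 were listed for control, 789 for Mn and 786 for MPP+. Uhrf2, which binds methylated DNA, was listed for both toxicants, and Mbd2, a methyl-CpG binding protein, for Mn alone. None of the 15 genes named beforehand was listed. Of 174 tests of the fixed lists against shuffled lists, 0 passed (smallest adjusted p = 1), and 2 had an unadjusted permutation p under 0.05: presynaptic genes among those listed for MPP+ and not control (3, with 0.707 from shuffling, p = 0.0276) and midbrain transcription factors among those for MPP+ (3, with 1.17 from shuffling, p = 0.0318).

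Probes with 10 spots made up 78.3% of the authors' deposited table and 4.58% of gene probes, and none of them was among the 45 filtered probes. The filter averages their 10 spots, so 1 bright spot counts for less than in a probe with 1 spot. Their absence thus says nothing about their genes. The lists shared 403 probes between control and Mn (382.0 from independent lists), 385 between control and MPP+ (380.4) and 446 between Mn and MPP+ (446.6). The lists for MPP+ and control were rebuilt from the scanner values by asking that a probe have at least 1 spot over a threshold on each array, which gave 885 of 885 probes for MPP+ and 773 of 777 for control. The threshold, on the spot mean minus background, lay at the lowest listed value of each array (157 beside 156 on control replicate 2). Recovery of the listed probes was thus largely fixed by that choice. For MPP+ every probe that passed was also listed, which the choice did not fix. The same held for control, but there the threshold above the lowest listed value on replicate 2 may have kept unlisted probes from passing.

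**Figure D3:**
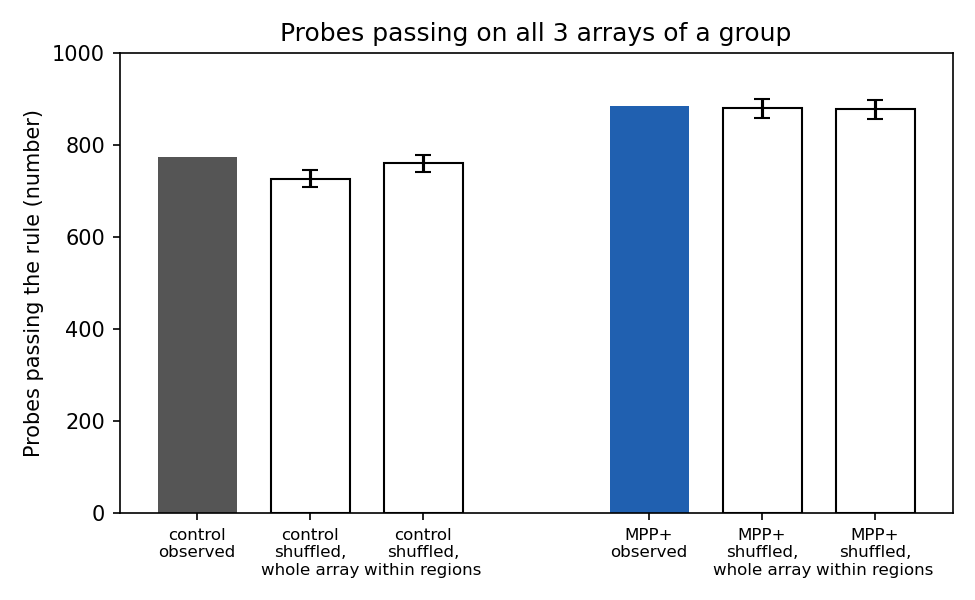
Number of probes with at least 1 spot over threshold on all 3 arrays of control and of MPP+ (filled bars), and the mean after spots were shuffled among probes 1000 times over the whole array or within regions of it (open bars, error bars 1 SD). For MPP+ 885 probes stand beside 879.5 shuffled, and for control 773 beside 726.7 over the whole array and 759.9 within regions.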

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

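The tests in this part were chosen after their results had been seen, apart from the spot pass rates of probes with 10 spots. The second channel of MPP+ replicate 3, which no comparison uses, had 2.78% of gene spots above background (95% Wilson interval 2.62 to 2.94), against 1.94% (1.81 to 2.08) in the array deposited as control replicate 3. Nothing in the labels says what that channel holds.

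Gene signals were hardly shared between arrays: the Spearman correlation of spot over background ran from -0.0109 to 0.0323 over 21 pairs and from -0.0097 to 0.0094 over the 5 pairs of 1 group, and that of raw spots reached 0.141. A grid of spots laid off the printed features would let the 10 spots of a probe match under another placement, but over 53125 placements per array (shifts up to 12 spots, stretch up to 6%) the highest intraclass correlation was 0.0205 (Mn replicate 1), with up to 0.0226 over 39 shufflings of probes on that array (one-sided permutation p = 0.1, and 0.2 to 1 on the other arrays). For control replicate 2 and the array deposited as control replicate 3 a misplaced grid stays open: shifted by 2 spot rows and 1 column they correlated at 0.0353, or 6.72 SDs over shifts, though laid together so their 10 spots reached an intraclass correlation of 0.0143, and 0.0157 with shuffled probes. Differences in methylation between cultures would leave those spots in accord within each array, provided that spots read their gene. Their correlation had an upper 95% limit of 0.0149 at most. If spots carried no gene signal, that limit would arise whether or not the cultures differed, so it cannot tell whether they did. Also open is that gene spots were as dim as spots that bind nothing: 3.40% of gene spots were above background and 3.11% of blank ones (2.68 to 3.62), which is consistent with signals at background, though control replicate 2 lay above its interval.

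Most probes in the authors' deposited table have 10 spots, among them Drd2, Bdnf, Hmox1 and Ndufv2. If these genes were more methylated and spots read their gene, single spots of such probes would pass more often than those of other probes. The ratio of pass rates was at most 1.04 over the arrays. If spots carried no gene signal, that ratio says nothing about methylation. More chances of 1 bright spot remain open: shuffled spots gave 766.2 probes with 10 spots for MPP+, and 786 were found (one-sided permutation p = 0.149). For control, shuffling over the whole array gave 726.7 probes against 773 found (one-sided permutation p = 0.00599), and shuffling within regions of the array 759.9 (p = 0.251), so bright regions shared by the control arrays may add to it. The 383 probes passing in both control and MPP+ stayed above the 357.5 from shuffling within regions (one-sided permutation p = 0.0460).

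Control replicate 3 and Mn replicate 3 hold the values of 1 array. That array gave 100% of the control replicate 3 column of the authors' deposited table and 3.86% of the Mn replicate 3 column, no more than other arrays gave (up to 4.61%). The array is then likely that of control, and the Mn replicate 3 column rests on values not used here. No biological explanation was tested, since the design gives none for equal values.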

How the results depend on the processing

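Alternatives that join no filter with another choice, leave out code 1 or 4, block on place along the slide or count the shared array as control were chosen after seeing the data. Signal over background limited the tests: 45 probes passed the filter, and a filter on all arrays left no probe. Counts of changed probes stayed at 0 in 64 of 75 alternatives. Leaving out 1 array gave 0 to 1 probe in each comparison (Rnase4 or Taf5l1), and the authors' deposited table gave 1 (Egf, MPP+ against control). Leaving out spots of code 1, which are the dim ones, called 3 probes in Mn against control (Rnase4, Taf5l1 and a probe without symbol), 4 in MPP+ against control (Rnase4, Higd1a, Nfil3, Mrgprf) and 2 in Mn against MPP+ (Taf5l1, Mrgprf), each with 1 value left in at least 1 of the groups compared. Place along the slide as a random block called 18, 19 and 13 probes in these comparisons in turn, with a correlation within places of -0.796. That fit is not reliable here: with unchanged simulated groups it called probes in 89 of 100 sets, and no block in 5. With no filter, leaving out 1 array gave 0 to 202 probes for Mn against control, 0 to 238 for MPP+ against control and 0 to 265 for Mn against MPP+. All such calls came where an arm kept 1 array, assumed to vary like the others, and in 1565 of 1570 the lone array was the brighter side. Camera or fry called 0 lists in 51 alternatives, the smallest adjusted p being 0.0554 without MPP+ replicate 2 in Mn against MPP+ (up to 0.920 over that comparison's alternatives). The planned list alternatives under the filter had no list to test. All 276 alternative values of the named genes kept their sign where the probe was still tested. All named probes but that of Snx29 were above background on just 3 arrays, so leaving out 1 of those arrays removed the probe. The sign was thus not checked without the arrays that carry it. For Taf5l1, Mn replicate 1 stood at 7.03, and control replicates 1 and 2 at 8.09 and 6.91. The log2 sizes moved: Mrpl57 ran from 0.75 to 3.72 in Mn against MPP+, Mrgprf from -3.19 to -1.05, Ctc1 from 0.43 to 1.20 in Mn against control, Snx29 from 1.17 to 3.73, and Rin3 from -1.88 to -0.43 in MPP+ against control. Over its alternatives the adjusted p of Rnase4 ran from 0.00686 to 0.998 for Mn and from 0.00204 to 0.795 for MPP+, and that of Taf5l1 from 0.00925 to 0.998 against control and from 0.00664 to 0.963 against MPP+ (limma). The correlation of log2 changes ran from 0.435 to 0.788 when 1 array was left out. It was 0.386 without code 1 and 0.547 with the random block. With no filter it ran from 0.453 to 0.719 when 1 array was left out. The lowest value with no filter was 0.421, with all 9 arrays as labelled. The difference in array level between MPP+ and control turned positive without background correction (0.20), with the spot mean (0.028) and within arrays of 1 channel (0.052), and ran from -0.26 to 0.067 when 1 array was left out. The cause was not tested. Whether arrays of equal replicate number belong together stays open: their deviations from group means correlated between -0.012 and 0.014, but deviations mirror each other in groups of 2 arrays, and the replicate 1 arrays share their column spacing (73.0) and have the highest level in each group. With the replicate block, limma called 0 probes in each comparison and the correlation was 0.520. The scan batch block, which sets MPP+ replicate 3 apart, also called 0 and gave that correlation.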

Other observations

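The values in this part belong to no planned comparison and were chosen after seeing the data. With no filter, the smallest p in Mn against control fell at Fam241b (at least 7.20-fold higher in Mn, adjusted p = 0.459 with limma), Tuba8, an alpha-tubulin (at least 3.01-fold brighter in control), and Clic2, a chloride channel family member (at least 4.19-fold higher in Mn). In MPP+ against control it fell at Tuba8 (at least 3.03-fold, adjusted p = 0.463 with limma), the olfactory receptor Or51a25 (at least 2.82-fold) and Ddr2, a collagen receptor (at least 5.36-fold), all brighter in control. In Mn against MPP+ it fell at Fam241b (at least 7.18-fold, adjusted p = 0.255 with limma), Nop58, a nucleolar protein (at least 2.92-fold), and Clic2 (at least 3.82-fold), all higher in Mn. Each of these probes was above background on 1 or 2 of 7 arrays. Fam241b, Ddr2 and Nop58 were so on 1 array. Their folds use a mean that includes an array where the probe did not exceed background by over 2 SDs.

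The inflammation list had 7 probes in the authors' deposited table for Mn, 6 for MPP+ and 2 for control, where shuffling gave 5.82, 5.73 and 4.90. Il1b had mean ratios of 1.98 ± 0.520 in Mn and 3.44 ± 0.672 in MPP+ (SD, n = 3), and Il6 3.55 ± 2.09 and 2.76 ± 0.937. These ratios and those below are also from single spots and are not read as gene levels. Apoptosis genes numbered 2 for Mn, 3 for MPP+ and 3 for control, where shuffling gave 5.39, 5.27 and 4.53. Among the unfolded protein response genes, Ddit4 had mean ratios of 3.18 ± 0.395 in Mn and 1.99 ± 0.886 in MPP+, and Eif2ak3 1.86 ± 0.733 and 2.68 ± 1.57, and neither was listed for control. Atf4 was listed for Mn alone and Derl1 for control alone. That list had 3 probes for Mn, 2 for MPP+ and 1 for control, where shuffling gave 1.88, 1.82 and 1.55.

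For Mn, 1879 probes passed on its 2 arrays used, with 1796.6 from shuffling over the whole array (one-sided permutation p = 0.00300) and 1845.1 within regions (p = 0.105). Spots were laid out with a column spacing of 73.0 on replicate 1 of each group and of 69.5 to 71.1 on the other arrays. Control replicate 2 and the array deposited as control replicate 3 correlated at 0.0353 when 1 was shifted by 2 spot rows and 1 column, against -0.0074 as deposited. That is 6.72 SDs over the 961 shifts of the pair, and the next highest of all pairs was 4.47 (MPP+ replicates 1 and 2). Control replicate 1 and Mn replicate 1 reached 0.0450, which is 2.13 SDs over their shifts. Spots of quality code 1, whose meaning is not given, made up 81.0% to 87.2% of spots on the 7 arrays, all with a diameter of 65. Of gene spots, 0.00273% to 0.0225% of those with code 1 were above background, and 27.8% to 70.2% of those with code 3. Spots above background in both channels of MPP+ replicate 3 numbered 95, with 20.7 from independent channels.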
